A study of Homo sapiens with 2 samples.

How the data were processed

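RNA immunoprecipitation followed by sequencing (RIP-seq) recovers the RNAs that travel with a chosen protein when an antibody pulls it from a cell lysate. Here the protein was IGF2BP3 (also called IMP3), a cytoplasmic RNA-binding protein of the IGF2BP family, and the cells were Ishikawa, an established human endometrial adenocarcinoma line. Per the labels' protocols, 80% of the lysate went into the immunoprecipitation (IP) with an anti-IGF2BP3 antibody and 10% was kept as input. A rabbit IgG control is mentioned there and was not analysed here. Per the labels' protocols, the libraries came from a stranded mRNA kit with unique molecular identifiers of 8 random bases and were sequenced as paired 150-base reads. There was 1 IP library and 1 input library, so no spread between replicates can be given.

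The authors deposited 1 annotated peak list. Per the file headers, it gives for each peak a gene name, a chromosome, a start, an end, a length, a strand, a region label and an annotated transcript. It gives no read count, fold enrichment, score or p-value for a peak, so depth and the strength of enrichment are unknown, and no peak could be ranked against another. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.3a, bedtools 2.25.0, deepTools 2.4.1 and HOMER 4.10 and the build GRCh38, with no role for each. The peak caller, its threshold, and whether the input library served as its background are not given in the sources used here. Both end positions belong to the peak, since end minus start plus 1 equals the length in 100% of the peaks. Positions were taken as 1-based, which was not tested. The length is therefore a genomic span, which includes any intron between the ends of a peak. The file has no legend for its region labels. They are printed here as 3' UTR, coding, 5' UTR, PR intron, NP exon and NP intron. Of the peaks labelled PR intron, 4861 carried a gene that RefSeq calls protein-coding, but so did 1000 peaks labelled NP intron, so NP is not the same as a non-coding gene.

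Gene names were matched to a RefSeq gene table of the assembly GRCh38.p14, which holds gene spans and gene classes but no strands, exons or sequence. Of the 6213 gene names, 5235 matched a current symbol, 223 matched through an unambiguous synonym and 755 did not match. Most of the unmatched names are clone-based, and 12 had been turned into dates. The unmatched names were kept apart and not called lncRNA. All 10321 peaks with a matched name lay on the chromosome RefSeq gives for it, and 9947 (96.4%) overlapped its span. A gene was called lncRNA where RefSeq gives lncRNA or antisense RNA.

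Shares of peaks were given with Wilson 95% intervals (scipy 1.17.1), which cover counting error only and describe this list, not repeated experiments. Of the 21 gene lists written before the data were examined, 19 held at least 5 protein-coding genes. List names were matched by symbol, then by synonym, with mitochondrial names sought on the mitochondrial genome alone and a shared synonym given to the only protein-coding gene that has it. The first matching, by symbol or unambiguous synonym, had lost the mitochondrial list and NDUFA4 of the oxidative phosphorylation list, and it was repaired after its results were seen. For each of these the share of genes with at least 1 peak was compared with that of all other RefSeq protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 19 lists and a threshold of 0.05. Expression decides whether a peak can be called, and no expression values were used here, so these tests compare lists within this peak list and say nothing of binding per transcript. A second comparison drew 10000 random lists with the same number of genes in each of 10 classes of RefSeq gene span which permutes list membership among genes of like span, and gave a two-sided permutation p and a Mantel-Haenszel odds ratio. Both were tested on simulated data over the 20056 protein-coding genes. Of 50 lists of 20 genes given an odds ratio of 6, Fisher's exact test called 43 and the span-matched test 46. Of 50 lists without an effect drawn from all genes, each test called 1. Of 50 lists without an effect drawn from the longest genes, Fisher's exact test called 6 and the span-matched test 0. The simulated chance of a peak was set by the same 10 span classes and drawn for each gene alone. The simulation therefore cannot test span within a class, expression or related genes in a list.

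The rule for named genes was to rank by fold enrichment, which the file does not give. In its place genes were ranked by their number of peaks, with ties in alphabetical order: the 10 genes with the most peaks, the 15 lncRNA genes with the most peaks and up to 4 members of each list. IGF2BP3, MALAT1, NEAT1, H19 and MYC were named whatever their values. The zinc finger list was drawn up from genes thought to have long 3' UTRs. Further genes were chosen after their values were seen. These are MUC16, SGMS1-AS1, TUG1, OIP5-AS1, CDKN2B-AS1, NORAD, SNHG7, CYTOR, METTL3, IGF2, ACTB, LIN28B and CTBP2. The genes UBE3A and TTN were also chosen so, for the peaks over them. A pair of lncRNA genes of this rank and 1 member of a fixed list are not reported here. The planned comparison of fold enrichment between lncRNA and mRNA peaks, the median peak value of each list and every stricter score or fold threshold could not be run for want of a value per peak. The motif search could not be run, since no genome sequence was used here. Computation used Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures matplotlib 3.10.9.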

Results

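The data were the peaks of 1 anti-IGF2BP3 RIP-seq library from Ishikawa cells, prepared beside 1 input library of the same cells. The stated purpose of the series was to find lncRNAs that interact with IGF2BP3. The list held 11585 peaks with 6213 gene names and 7939 annotated transcripts. Of these peaks, 6101 were on the plus strand and 5484 on the minus strand. The identifiers run to peak 35577, and the listed peaks make up 32.6% of that number; the other numbers were not analysed here. Library totals are unknown, as are counts per peak.

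Peaks fell mainly on protein-coding genes, and among the 3' UTR, coding and 5' UTR labels the 3' UTR was the most frequent. RefSeq protein-coding genes carried 9707 peaks, or 83.8% (95% interval 83.1 to 84.4). The 3' UTR label covered 3103 peaks on 1922 genes, or 26.8% of all peaks (26.0 to 27.6). The coding label covered 479 peaks on 388 genes, or 4.13% (3.79 to 4.51), and the 5' UTR label 50 peaks, or 0.432% (0.328 to 0.569). Introns held the largest share, with 5144 PR intron peaks (44.4%, 43.5 to 45.3) and 2001 NP intron peaks (17.3%, 16.6 to 18.0). NP exons held 808 peaks, or 6.97% (6.52 to 7.45). The median span was 750 bases for 3' UTR peaks, 15776 bases for PR intron peaks and 6539 bases for NP intron peaks. Among the 5355 peaks with a span of up to 2000 bases, a subset chosen after the spans were seen, the 3' UTR share was 49.99% (48.7 to 51.3) and that of both intron labels together 28.8% (27.6 to 29.99). In this subset 3' UTR peaks outnumbered coding peaks by 2677 to 398. The lengths of 3' UTRs and coding regions were not used here, so these ratios are not densities.

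**Figure D1:**
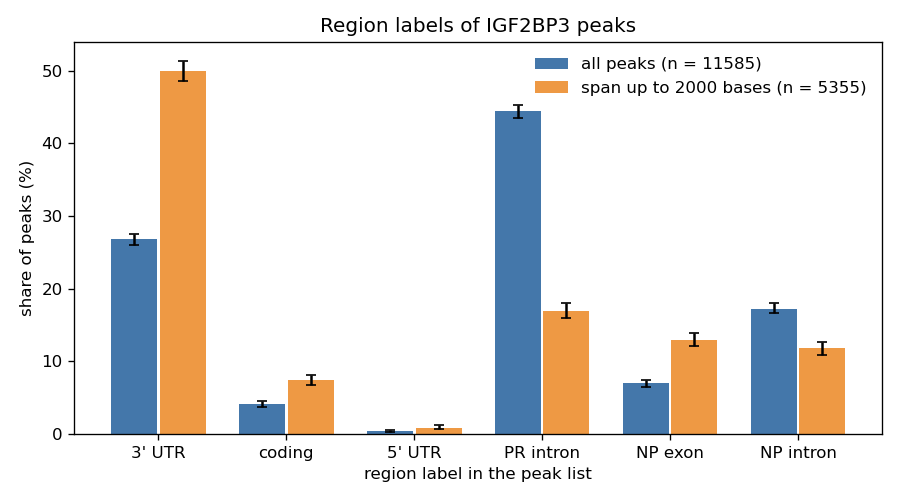
Share of peaks (%, y axis) with each region label of the peak list (x axis), for all 11585 peaks and for the 5355 peaks with a span of up to 2000 bases; error bars are Wilson 95% intervals. The 3' UTR share is 26.8% of all peaks and 49.99% of the short ones, and the PR intron share is 44.4% and 16.97%.

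Single genes carried from 1 to 39 peaks, and 3320 gene names (53.4%) carried 1. The gene with the most peaks was PCDHGA3, with 39 peaks labelled PR intron between positions 141346490 and 141512979 of chromosome 5 (GRCh38). It belongs to the gamma protocadherin cluster, cell adhesion genes that share their last exons, and the assignment of its peaks to single members was not tested. Of the 39, 18 overlapped another peak of the same strand by at least 50% of the longer of the pair, so the count includes near copies. PCDHAC1, of the alpha protocadherin cluster, carried 14 peaks, all labelled 3' UTR and all between positions 141010214 and 141010733, so they are near copies of 1 region. In the list as a whole, 307 peaks overlapped another peak of the same strand by at least 50% of the longer of them. In most of the other entries among the 10 genes with the most peaks, the label 3' UTR was the most frequent. Whether the peaks of a gene lie on 1 and the same 3' UTR was not tested. ARIH1, an E3 ubiquitin ligase, carried 13 peaks, of which 12 were in the 3' UTR. AGO3, an Argonaute protein of the microRNA pathway, CNKSR3, a scaffold protein, and ZBTB37, a zinc finger protein, each carried 11 peaks with 10 in the 3' UTR. PPP1R12B, a regulatory subunit of myosin phosphatase, carried 11 with 7 in the 3' UTR. The 10 genes with the most peaks also included the lncRNA genes TTN-AS1 (21 peaks) and SNHG14 (13 peaks), and the unmatched name CH17-140K24.2 (17 peaks, of which 14 overlapped a RefSeq protein-coding gene). MUC16, the CA125 antigen used as a tumour marker, was named after its values were seen. It carried 10 peaks, all labelled coding and all on the minus strand of chromosome 19 between 8936118 and 8977742.

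For the lncRNA question, 398 peaks on 212 genes carried the name of a RefSeq lncRNA or antisense RNA gene. This is 3.44% of all peaks (95% interval 3.12 to 3.78). A further 1264 peaks on 755 names had no RefSeq match and so no class here. Of the 398 lncRNA peaks, 269 were labelled NP intron (67.6%, 62.8 to 72.0) and 107 NP exon (26.9%, 22.8 to 31.4). Most of them, 242 (60.8%, 55.9 to 65.5), also overlapped the span of a protein-coding gene. Of the 212 lncRNA genes, 73 (34.4%, 28.4 to 41.1) had every peak clear of protein-coding genes. Without the lncRNA peaks over protein-coding genes, the lncRNA share was 1.35%, and with the unmatched names counted as lncRNA it was 14.3%. Of the 1264 unmatched peaks, 955 (75.6%, 73.1 to 77.8) also overlapped the span of a protein-coding gene. The 14.3% can therefore not be read as peaks on lncRNAs alone.

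Among the named lncRNAs, LINC00665 carried 5 peaks, all on the minus strand of chromosome 19 between positions 36313096 and 36331569, inside its RefSeq span and clear of protein-coding genes. LINC02693 (C17orf51 in the list) carried 5 peaks on the minus strand, clear of protein-coding genes. Of these, 3 were labelled 3' UTR and 2 ran past the edge of its RefSeq span. NUTM2B-AS1 carried 5 peaks clear of protein-coding genes, 1 on the plus and 4 on the minus strand, of which 2 lay outside its RefSeq span. FTX, a transcript of the X inactivation centre, carried 4 peaks clear of protein-coding genes, 1 on the plus and 3 on the minus strand, of which 1 ran past the edge of its RefSeq span. SNHG14, the long host transcript of small nucleolar RNAs in the Prader-Willi and Angelman region, carried 13 peaks between positions 24982014 and 25356821 of chromosome 15, 9 on the plus and 4 on the minus strand. Of these, 3 peaks on the minus strand lay in the span of UBE3A, a ubiquitin ligase gene. HOXA-AS3 and IPO9-AS1 carried 7 peaks each, all over protein-coding genes. CCDC144NL-AS1 carried 7 peaks, with 2 over protein-coding genes and 2 outside its RefSeq span, and SVIL-AS1 carried 5 with 3 over them. MCPH1-AS1 carried 5 peaks, and LINC00963, PITRM1-AS1 and SAP30L-AS1 carried 4 each, all over protein-coding genes. MIR570HG (LINC00969 in the list) carried 4, with 2 over them and 3 outside its RefSeq span. Peaks of HOXA-AS3, IPO9-AS1, CCDC144NL-AS1, SVIL-AS1 and MCPH1-AS1 lay on both strands. SGMS1-AS1, named after its values were seen, carried 4 peaks labelled NP exon on the plus strand of chromosome 10 between 50631371 and 50635781, with spans of 212 to 631 bases and no protein-coding gene beneath them. Of these, 3 lay outside its RefSeq span (50624951 to 50631636).

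TTN-AS1 carried the most peaks of any lncRNA name, with 21, all labelled NP intron. All 21 lay inside the RefSeq span of TTN, the titin gene (chromosome 2, 178525989 to 178807423), and no peak there was named for TTN. Of these peaks, 16 were on the minus strand and 5 on the plus strand. Gene strands were not used here, so which of them belong to TTN-AS1 and which to TTN was not tested. All 16 of the minus strand overlapped another peak of that strand by at least 50% of the longer, so the count of 21 includes near copies. In a comparison made after the data were seen, of the lncRNA genes with at least 2 peaks 31 of 86 (36.05%, 26.7 to 46.6) had peaks on both strands. Among protein-coding genes it was 338 of 2474 (13.7%, 12.4 to 15.1, two-sided Fisher's exact test over genes, p = 2.97e-07). Most lncRNA peaks (60.8%) lay over a protein-coding gene, and peaks per gene were not matched. The difference may thus reflect how peaks were named where genes overlap, which was not tested.

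**Figure D2:**
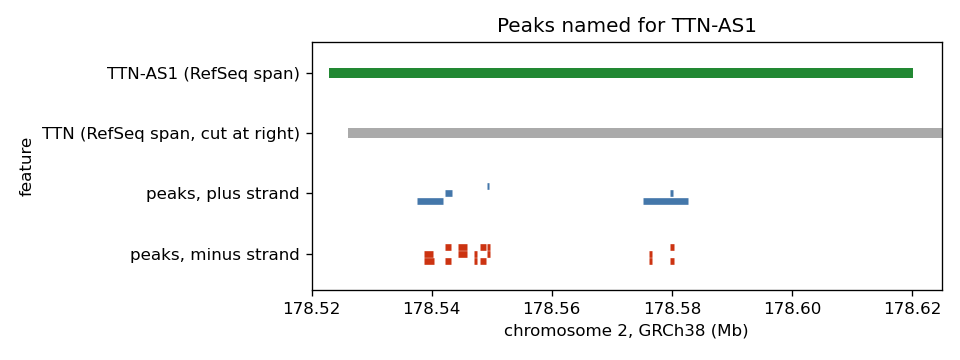
Map of chromosome 2 (GRCh38, x axis in Mb) with the RefSeq spans of TTN-AS1 and TTN and the 21 peaks named for TTN-AS1, by strand. The 16 minus-strand and 5 plus-strand peaks all lie inside the span of TTN.

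Of the 53 long-studied lncRNAs fixed as a list, 16 had a peak that carried their name. The name alone does not place a peak on the lncRNA. The single peaks of SNHG7 and CYTOR (LINC00152 in the list) lay outside their RefSeq spans, that of SNHG7 over protein-coding genes. Of those described here, SNHG7, CYTOR, TUG1, NORAD, OIP5-AS1 and CDKN2B-AS1 were named after their values were seen. TUG1, widely described as a lncRNA, carried 3 peaks, 2 on the plus and 1 on the minus strand. RefSeq calls it protein-coding, so they are not among the 398 lncRNA peaks. NORAD, a cytoplasmic lncRNA that binds Pumilio proteins, carried 1 NP exon peak of 5340 bases (chromosome 20, 36045621 to 36050960). OIP5-AS1 carried 2 peaks and SNHG16, a small nucleolar RNA host gene, carried 3, on exon and intron labels. CDKN2B-AS1, the antisense transcript of the CDKN2A/CDKN2B locus, carried 1 NP intron peak on the minus strand, over a protein-coding gene (chromosome 9, 22003529 to 22009363). Gene strands were not used here, so whether this peak belongs to CDKN2B-AS1 or to that gene was not tested. MALAT1 and NEAT1, abundant nuclear lncRNAs, and H19, an imprinted lncRNA, carried no peak in the list analysed here, under any gene name. No peak carried the name of any of the 16 structured small RNAs of the fixed list.

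For protein-coding genes, 5118 of 20056 (25.5%, 24.9 to 26.1) carried at least 1 peak, and 7 of the 19 fixed lists passed the threshold. In 5 of them genes with a peak were more frequent than among other genes, and in 2 less frequent. The share depended on gene span. It was 2.34% (1.77 to 3.10) in the decile of the shortest genes (median 1.62 kb) and 45.1% (42.9 to 47.2) in the decile with a median of 110 kb. With lists matched on span, 2 of the 7 lists still passed. With spans of up to 2000 bases only, 1 list passed, that of endometrial carcinoma, and with 3' UTR peaks only, 0 passed. Peaks of ELAVL1, RPL27A, RPL31, PXN, HMGA2, CD44, NDUFS1 and ZNF800, named below, lay on both strands. Gene strands were not used here, so counts are per gene name and not per transcript. Peaks on 1 strand only, such as the plus-strand peak of HNRNPU, were not checked against the strand of their gene either.

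**Figure D3:**
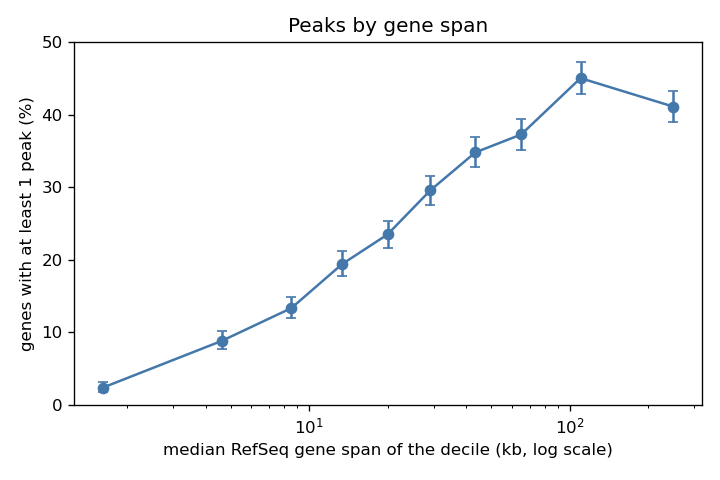
Share of RefSeq protein-coding genes with at least 1 peak (%, y axis) in each decile of gene span (x axis, median span in kb, log scale); error bars are Wilson 95% intervals. The share goes from 2.34% to 45.1% at the ninth decile and is 41.1% at the tenth.

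Genes of the m6A machinery, which adds, removes or reads N6-methyladenosine in mRNA, carried peaks in 12 of 18 cases (66.7%, 43.7 to 83.7; odds ratio 5.85, adjusted p = 0.00134 by Fisher's exact test). The list passed with span matched too (odds ratio 5.28, 1.93 to 14.4, adjusted p = 0.0228 by the permutation test). ALKBH5, a demethylase, carried 3 peaks, METTL14, a subunit of the methyltransferase, carried 2 in its 3' UTR, and VIRMA, a writer component, and YTHDF1, a reader, carried 2 each. METTL3, the catalytic subunit, named after its value was seen, carried none. The zinc finger list carried peaks in 12 of 18 genes as well (odds ratio 5.85, adjusted p = 0.00134 by Fisher's exact test, and 4.96, 1.75 to 14.0, adjusted p = 0.0228 with span matched). Its members were chosen with long 3' UTRs in mind, so they do not stand for zinc finger genes at large. ZNF148 and ZNF704 carried 4 peaks each, ZNF800 carried 3 and ZNF207 carried 2. Counting 3' UTR peaks only, neither list passed (odds ratio 2.73 and adjusted p = 0.401 by Fisher's exact test for each).

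The IGF2BP proteins and their known associates carried peaks in 10 of 15 genes (66.7%, 41.7 to 84.8; odds ratio 5.85, adjusted p = 0.00358 by Fisher's exact test). All 3 members of the IGF2BP family were among them with 1 peak each. The peak of IGF2BP3 itself spanned 160021 bases, from 23310238 to 23470258 on the minus strand of chromosome 7, nearly the whole RefSeq gene (23310209 to 23470491). Such a peak is not particular to IGF2BP3. Of 4882 PR intron peaks with a matched name, 1838 (37.6%) covered most of their gene. Another peak, on the plus strand and under a different name, also lay in the span of IGF2BP3. ELAVL1, the RNA-stabilising protein HuR, carried 3 peaks, of which 2 were in the 3' UTR, STAU1, a double-stranded RNA-binding protein, carried 2 and HNRNPU, a nuclear RNA-binding protein, carried 1. With span matched this list did not pass (odds ratio 4.28, 1.38 to 13.3, adjusted p = 0.117 by the permutation test). With spans of up to 2000 bases 2 of the 15 genes carried a peak (odds ratio 1.01, adjusted p = 1 by Fisher's exact test), and with span matched as well the odds ratio was 0.733. With 3' UTR peaks only it was 1.47 (adjusted p = 0.836 by Fisher's exact test).

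Of the known target RNAs of the IGF2BP family, 10 of 19 protein-coding genes carried a peak (52.6%, 31.7 to 72.7; odds ratio 3.25, adjusted p = 0.0444 by Fisher's exact test). HMGA2, a chromatin protein, carried 5 peaks, all labelled PR intron, 2 on the plus and 3 on the minus strand. BTRC, an F-box protein, carried 4 with 3 in the 3' UTR. CD44, a hyaluronan receptor, carried 3, all labelled PR intron, of which 2 were on the plus and 1 on the minus strand. A 3' UTR peak was present in 3 of the 19 genes (odds ratio 1.79, adjusted p = 0.794 by Fisher's exact test). MYC had no peak over its RefSeq span in the list analysed here, nor had IGF2, ACTB and LIN28B, named after their values were seen. With span matched the list did not pass (odds ratio 2.44, 0.967 to 6.14, adjusted p = 0.252 by the permutation test). Genes recurrently mutated in endometrial carcinoma carried peaks in 14 of 22 cases (63.6%, 43.0 to 80.3; odds ratio 5.12, adjusted p = 0.00134 by Fisher's exact test). The regulatory PI3-kinase subunit PIK3R1 carried 6 peaks, the transcriptional regulator ARID5B and the ubiquitin ligase subunit FBXW7 carried 4 each and BCOR, a corepressor, carried 3. With span matched, the odds ratio was 2.84 (1.17 to 6.90, adjusted p = 0.167 by the permutation test).

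Cytosolic ribosomal protein genes carried few peaks, 6 of 78 (7.69%, 3.57 to 15.8; odds ratio 0.242, adjusted p = 0.00134 by Fisher's exact test). RPL27A carried 4, RPL37 carried 3, RPL31 carried 2 and RPL23A carried 1. These genes are short, with a median span of 4.91 kb, and with span matched the odds ratio was 0.729 (0.310 to 1.72, adjusted p = 0.862 by the permutation test). Of the 16 leukocyte markers, included as genes of a cell type that a carcinoma line should lack, none carried a peak, which leaves a share of up to 19.4% (adjusted p = 0.0476 by Fisher's exact test, 0.252 with span matched). Nuclear-encoded oxidative phosphorylation genes carried a peak in 1 of 22 cases, NDUFS1 of complex I (odds ratio 0.139, adjusted p = 0.0587 by Fisher's exact test). None of the 13 mitochondrially encoded mRNAs carried a peak, which leaves a share of up to 22.8% (adjusted p = 0.103 by Fisher's exact test). At the same gene spans 2.34% were expected to carry one. That share comes from short genes of any expression, so it cannot say whether the absence is unusual for these mRNAs. No listed peak lay on the mitochondrial genome.

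The other 10 lists did not pass the threshold. Mitotic genes carried peaks in 9 of 22 cases, among them ANLN, CENPE and MKI67 with 3 each and AURKA with 2. Replication genes did so in 5 of 22, among them the transcription factor E2F3 with 4 peaks, of which 3 were in the 3' UTR. Epithelial keratin and adhesion genes had 8 of 18, with CDH1 (E-cadherin), CTNND1 (p120 catenin) and DSP (desmoplakin) at 3 peaks each. Integrin, laminin and focal adhesion genes had 9 of 21, with the adaptor PXN (paxillin) at 3, and glycolysis and hypoxia genes 9 of 24, with PGK1 at 3, all in the 3' UTR. Estrogen and progesterone response genes had 4 of 16, with CA12 and STC2 at 3 peaks each. Translation factors had 5 of 18, with the cap-binding protein EIF4E at 5 peaks, of which 4 were labelled 3' UTR. Most of these 4 overlapped no RefSeq protein-coding gene and so lay outside the RefSeq span of EIF4E. Mesenchymal and matrix genes had 2 of 18 (SPARC and ZEB1), ER chaperones 2 of 17 (CANX and SEL1L) and cytosolic chaperones 1 of 12 (BAG3). Adjusted p over these 10 lists ranged from 0.152 to 1 by Fisher's exact test.

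**Figure D4:**
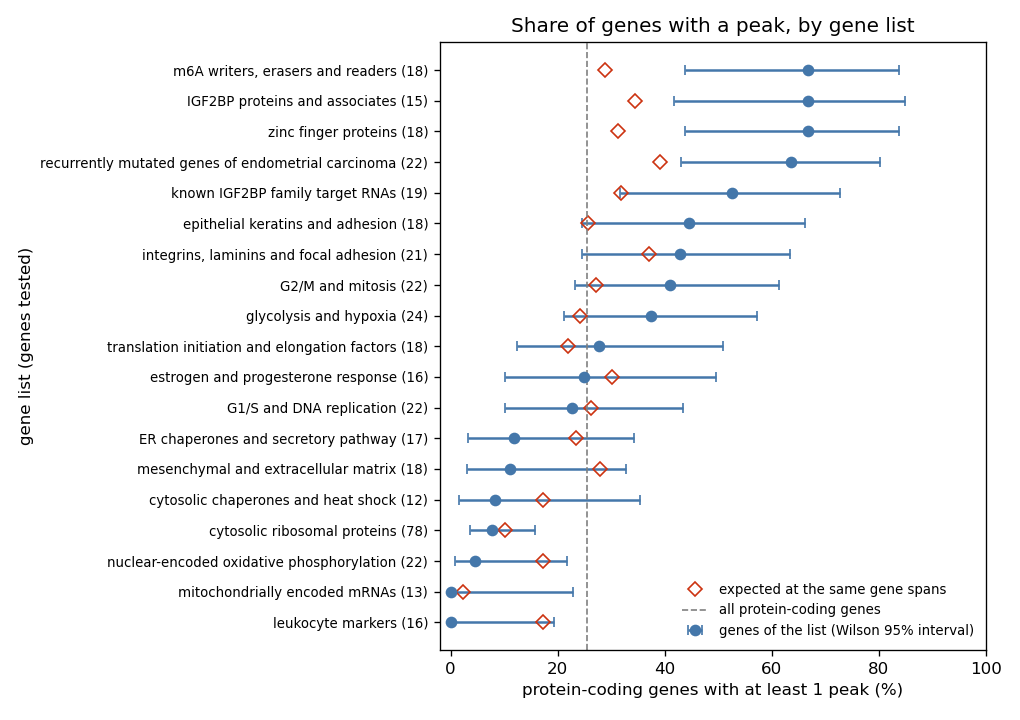
Share of protein-coding genes with at least 1 peak (%, x axis) in each fixed list (y axis, genes tested in brackets), with Wilson 95% intervals as error bars; diamonds are the share expected at the same gene spans and the dashed line is all protein-coding genes (25.5%). The m6A list and the zinc finger list, at 66.7%, lie above expected shares of 28.8% and 31.3%.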

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

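With 1 library per group no replicate could be left out, and no test across libraries exists. No paired analysis was possible because each group holds 1 library. Depth could not be weighed, since no counts were given. The stricter score and fold thresholds, the best peak per gene, exon-based assignment, the comparison of the best-scored genes with the rest, random lists matched on peaks per gene and all motif controls were not run for want of a score, exons or sequence. Every alternative here was chosen after seeing the data except the main chromosomes, the merging, the peak bases and the midpoint rule for lncRNA genes outside protein-coding genes. The number of peaks was 11579 on the main chromosomes and 10146 after merging, but 5355 with spans of up to 2000 bases, and the number of genes fell from 6213 to 3347 there. The lncRNA share (3.44%) was 3.04% for midpoints in a RefSeq lncRNA gene outside protein-coding genes, 10.5% for midpoints in any lncRNA gene, 14.3% with unmatched names added, 1.35% without peaks over protein-coding genes, 4.28% for spans of up to 2000 bases and 3.41% with 1 peak per gene. The shares of the 3' UTR, coding, 5' UTR, intron and NP exon labels were 28.5%, 4.97%, 0.644%, 56.7% and 9.19% with the shortest peak of each gene. They were 1.66%, 0.272%, 0.0130%, 97.6% and 0.414% of peak bases, which long spans dominate by construction. They were 49.99%, 7.43%, 0.896%, 28.8% and 12.9% for spans of up to 2000 bases, and 49.8%, 7.96%, 1.14%, 26.6% and 14.5% for spans of up to 1000 bases. In the order of the shares, introns led the 3' UTR over all peaks and the 3' UTR led introns among short spans. The number of gene lists past the threshold, 7 of 19, was 7 of 18 with the first matching of list names, where the oxidative phosphorylation list had an adjusted p of 0.0548 by Fisher's exact test against 0.0587. It was 2 with span matched, 1 with spans of up to 2000 bases (the endometrial carcinoma list, odds ratio 4.55) and 0 with 3' UTR peaks only, where 1 list had an unadjusted p below 0.05 by Fisher's exact test. Lists that no longer passed with span matched had odds ratios of 2.44 (IGF2BP targets), 4.28 (IGF2BP proteins and associates), 2.84 (endometrial carcinoma), 0 (leukocyte markers) and 0.729 (ribosomal proteins). With spans of up to 2000 bases these were 1.75 for IGF2BP targets, 1.01 for IGF2BP proteins and associates, 3.29 for the m6A list, 0 for leukocyte markers, 2.53 for zinc fingers and 0.448 for ribosomal proteins. With 3' UTR peaks only they were 1.79, 1.47, 2.73, 0, 2.73 and 0.514 in the same order, and 4.46 for endometrial carcinoma. Both last settings leave fewer genes with a peak and so less power, and the cause was not tested further. With spans of up to 2000 bases and span matched as well, 0 lists passed, with 1.45, 0.733, 2.95, 0, 2.10 and 1.002 in that order and 2.999 for endometrial carcinoma. With 3' UTR peaks only and span matched, 0 passed, with 1.46, 1.03, 2.36, 0, 2.30 and 1.42 in that order and 2.84 for endometrial carcinoma. The IGF2BP proteins (0.733) and, in both joint settings, the ribosomal proteins thus lay on the other side of 1 from their main values, with no adjusted p below 0.05 by the permutation test.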

Other observations

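The family scan, the ZNF genes outside the fixed list, the mitochondrial copies, the chromosome shares and the test of short intronic spans were chosen only after the result was seen. For the other tests of spans, strands and gene span, what each outcome would mean was written before its value was known, though after the peak list had been explored. Gene families were formed by the letters that begin a RefSeq symbol. Of 73 families with at least 25 protein-coding members, 27 passed the threshold by Fisher's exact test without span matching. Against random sets of genes of the same spans 12 differed after adjustment, 6 with more genes carrying a peak and 6 with fewer. The ZNF family had peaks on 219 of its 517 genes (42.4%, 38.2 to 46.7), where 26.6% were expected at these spans (odds ratio 2.13, 1.78 to 2.56, adjusted p = 0.00292 by the permutation test). Among the 499 ZNF genes outside the fixed zinc finger list the share was 41.5% against an expected 26.5% (odds ratio 2.07, 1.72 to 2.49, permutation p = 0.0002, the smallest these random sets can give). With 3' UTR peaks only, 57 of the 499 carried one (11.4%, against 9.44% of other genes, p = 0.141 by Fisher's exact test). ZBTB transcription factors (20 of 42 genes), RNF ubiquitin ligases (37 of 85), UBE ubiquitin-conjugating enzymes (22 of 42), VPS vesicle sorting proteins (19 of 35) and PPP phosphatase subunits (33 of 77) were the other families above expectation, with adjusted permutation p from 0.00730 to 0.0385.

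Among the families below expectation, no olfactory receptor (OR, 392 genes) carried a peak, against an expected 8.92%. Peaks were on 3 of 56 CYP genes, 5 of 44 COL genes, 4 of 51 CFAP genes, which encode cilia and flagella proteins, 1 of 55 KRT genes and 11 of 91 CD genes. Expression of these genes was not measured here, and symbol stems mix unrelated genes in places.

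Introns dominated the region labels, and the spans of these peaks bear on what the label says. Peak spans up to 1000 bases clustered on a grid: 50.7% of those with exonic labels (48.9 to 52.5) were a multiple of 30 plus 0 or 1 bases, where chance gives 6.67%, as windows moved in steps would leave. Of the 4814 intronic-labelled peaks over 5000 bases, 6.52% (5.86 to 7.26) were on the grid, consistent with spans that cross splice junctions, so that the label may describe the span and not the bound bases. Of the 1051 intronic-labelled peaks of up to 1000 bases, 42.9% (40.0 to 45.9) were on it, which argues against junctions as the cause there and leaves unspliced RNA, unannotated exons or the choice of transcript open as untested. At 1000 to 5000 bases 24.7% of exonic-labelled peaks (22.5 to 27.0) and 9.38% of intronic-labelled ones (7.90 to 11.1) were on it, but exonic-labelled peaks over 5000 bases were near chance too (13 of 153), so another reason for losing the grid with length stays open.

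On opposite strands, 254 peaks overlapped a peak of the other strand by at least 50% of the longer of the pair, and 120 of them were labelled 3' UTR. Their midpoints lay in 2 or more RefSeq genes in 63.4% of cases (57.3 to 69.1), against 15.4% (14.8 to 16.1) of the other peaks, a ratio of 4.104 (3.70 to 4.55). Both peaks of a pair were counted though they share a place, so the intervals of the paired share and of the ratio are too narrow. The ratio met the rule set against reads placed on the wrong strand wherever a peak lies as the whole cause. It cannot settle this, since only 32.6% of the peak numbers are listed and how these were chosen is unknown. If peaks were kept only where their strand has an annotated gene, wrong-strand peaks would remain mainly where genes overlap. A candidate explanation is transcription of overlapping genes in opposite directions. Wrong-strand reads stay open, also because the RefSeq table used has no strands. CTBP2 had 6 such peaks and TTN-AS1 had 9.

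Gene span could account for part of the list results. With span matched, the odds ratio of the ribosomal protein list moved from 0.242 to 0.729 (0.310 to 1.72), so the shortness of these genes is a candidate explanation for their few peaks. Short genes include families without any peak, such as the olfactory receptors (0 of 392, expected 8.92%). Expression was not matched, so this comparison cannot tell gene span from expression. For the m6A list (5.28) and the zinc finger list (4.96) the matched test passed, which argues against gene span as the whole cause. The lengths of 3' UTRs were not used here, and they stay open for the zinc finger list, chosen with long ones in mind. For the IGF2BP targets (2.44), IGF2BP proteins and associates (4.28), endometrial carcinoma genes (2.84) and leukocyte markers (0), the matched test did not pass after adjustment, though the intervals of the associates (1.38 to 13.3) and the carcinoma genes (1.17 to 6.90) exclude 1, so the part of gene span stays open. Expression, which was not measured here, stays open for every list.

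Of the 7 peaks named RP5-857K21.4, 6 lay between positions 629061 and 634922 of chromosome 1 over RefSeq pseudogenes of mitochondrial genes, among them MTND1P23, MTND2P28 and MTCO1P12, while no listed peak was on the mitochondrial genome. By chromosome, the share of protein-coding genes with a peak ran from 18.0% on chromosome 21 to 39.3% on chromosome 18. Without span matching several chromosomes passed the threshold by Fisher's exact test, some with a higher share (chromosome 18, adjusted p = 7.93e-06) and some with a lower one (chromosome 19, adjusted p = 1.54e-08). With span matched no chromosome of the 23 compared passed it (smallest adjusted p = 0.0966 by the permutation test, chromosome 12, with 4 chromosomes at 0.110).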
